A study of Homo sapiens with 6 samples.

How the data were processed

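The screen paired guide RNAs in 1 construct so that a cell that took it up could lose 2 genes at once. Genomic DNA of the cells was the template of a PCR over the guide locus, and the amplicons were sequenced. The 6 libraries fall into 3 groups of 2 replicates, which are day 0, day 14 without irradiation and day 15 with repeated irradiation. Groups and replicate numbers were taken from the sample titles.

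The deposited values are whole-number read counts per pair of guides, not normalised, per the file headers and from the values themselves. Guide pairs with 0 reads are not listed in a library's table and were set to 0 here. The submitters' processing notes name HISAT2 2.1.0 and genome build hg38, and do not say which step used them. How reads were assigned to guides, and any filter on them, is not given in the sources used here. The deposited counts of the irradiated libraries came in another combined table than those of the day 0 and day 14 libraries. In each of the 6 libraries, 0 guide pairs differed between its own table and the combined one. The combined tables also hold 2 columns that match no sample of the series, and these were not used here.

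Guide names gave the design of the library. A name holds a gene symbol and a guide number, or marks a non-targeting control. Guides 1 and 2 of a gene were read at position 1 of the construct, guides 3 and 4 at position 2, and non-targeting guides at both. The symbols are written as mouse symbols (Trp53, for example), although the cells are human. Of the 459 gene names, 445 matched a current human symbol and 8 an older one, and 6 matched none or were ambiguous. Names are given as the tables write them. Guide sequences, and with them the positions of the target sites in the genome, were not used here.

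For single knockouts, the counts of all constructs with a guide of the gene at one position and a non-targeting guide at the other were summed per gene and library. Libraries were scaled by their total count of constructs with non-targeting guides at both positions. Of these constructs, 69.7% had no reads in day 14 replicate 1 and 66.6% in irradiated replicate 2. Genes needed a mean summed count of at least 20 over the 6 libraries. The test was edgeR's quasi-likelihood test, two-sided, fitted to all 6 libraries at once, with Benjamini-Hochberg adjustment and a threshold of 0.05. For double knockouts, counts were summed per pair of different genes over both orders. The effects of both genes in each library, from an additive fit of medians over all partners on log2 CPM values (prior count 2, 25 iterations), entered edgeR as an offset. The fitted contrast is then the interaction, the log2 change of the double knockout minus the sum of both single changes.

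Before the data were examined, 17 lists of DNA repair, replication and chromatin genes, 89 gene pairs with a commonly described interaction, these tests, most alternatives and the rule for naming genes were fixed. Each list was tested with camera (preset correlation 0.01, then an estimated one), which compares its members with all other genes, and with fry, which asks whether its members move one way. The direction given by camera can therefore differ from the sign of a list's mean where that mean lies close to the median of all genes. The mean change of a list with its 95% interval came from a limma fit to the members' mean log2 value per library. By the rule, the text names the genes past the threshold with the largest changes of one sign in all library comparisons, up to 4 members of smallest p per list, and a fixed set of 14 repair genes, of which 13 were measured. For gene pairs it names those past the threshold, or the 3 of smallest p where none passed. Some genes and pairs that these rules name are not reported here.

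Tests of each guide, summed over all its partners, were added after the data were examined. They took 1849 guides with a mean count of at least 2000, scaled by TMM (edgeR's trimmed mean of M-values) within each position. The guides named from them were chosen after their values were seen.

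Total counts ran from 61185707 to 86587125 reads per library. The single-knockout sums had a biological coefficient of variation of 0.14 between replicates and a median 95% half-width of 0.40 on the log2 scale. The gene tests were checked on simulated data for day 14 against day 0 over the 459 genes. In counts drawn from the model with 200 genes changed, 68.7% of 1.5-fold and 100% of 2-fold changes were recovered, and 13 of 259 unchanged genes were called. In the real counts thinned by a factor of 2 in both day 14 libraries, 95.5% of 200 and 93.3% of 30 genes were recovered. The interaction test, with a coefficient of variation of 0.473, recovered 2% of 4-fold and 35% of 16-fold changes in drawn counts, and 0% of either in thinned real counts over 105111 gene pairs. The guide test recovered 78% of 1.5-fold and 86% of 2-fold changes in thinned counts for 200 of 1849 guides. It also called 13 and 12 of the guides that were not thinned. Recovery where only a few guides change was not checked.

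Intervals printed with changes of genes, lists, gene pairs and guides come from the spread between libraries. Those of guide correlations, of shares of missing guide pairs and of the other guide pairs of a gene pair are bootstrap intervals. They resample genes, control guides or guide pairs and hold no spread between libraries. The reads are PCR products, and the labels name no molecular identifiers, so read counts are not counts of independent molecules, and an interval from counts alone would cover counting error only. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. The replicates of each group differed far beyond sampling noise, with a chi-square per degree of freedom of 15.2, 67.5 and 76.2.

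Alternatives changed the scaling (TMM, total reads), the filter, the constructs summed, the position of the guide, the libraries in the fit, the replicate number as a block, the number of population doublings and the tool (DESeq2 for genes, limma-trend for gene pairs), and left out each library in turn. Constructs with guides of the same gene at both positions were not tested. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.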

Results

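The screen measured how pairs of gene knockouts in the DNA repair network fared in eHAP cells, a human line derived from the near-haploid leukemia line HAP1. The clone carried Cas9 under doxycycline control and lacks p53, per the labels. Each construct held 2 guide RNAs, and its read count stands for the abundance of the cells that carried it. Cells were collected at day 0, after 14 days and 12 population doublings of standard growth, or after 15 days and 10 doublings with 0.6 Gy of X-rays given a day after each split. The labels give 2 different lethal-dose figures for this treatment. The library held 863546 guide pairs with reads in at least 1 library, from 1826 guides of 459 genes, mostly 4 per gene, and 61 non-targeting guides. Single knockouts were read from a median of 121 constructs per gene that paired a gene's guide with a non-targeting guide.

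Day 0 replicates 1 and 2 held 84399152 and 86542435 reads, the day 14 replicates 61962789 and 61185707, and the irradiated replicates 71481191 and 86587125. Coverage of the library differed within groups. At day 14, 54.1% of guide pairs had no reads in replicate 1 and 5.6% in replicate 2. After irradiation, 7.6% had no reads in replicate 1 and 49.4% in replicate 2, whereas at day 0 the shares were 4.7% and 1.9%. The log2 counts of the 2 incomplete libraries, day 14 replicate 1 and irradiated replicate 2, correlated over guide pairs with r = 0.673, against 0.395 between the day 14 replicates and 0.409 between the irradiated ones. Guide pairs are not independent replicates.

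**Figure D1:**
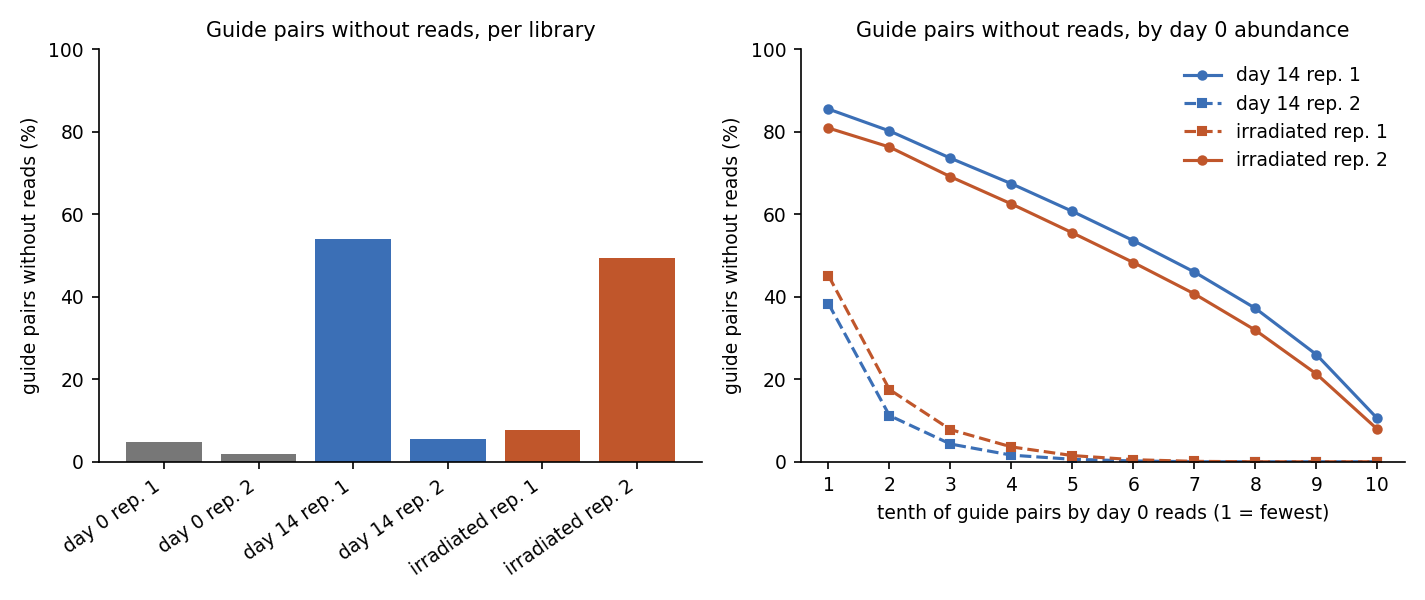
Left, percentage of guide pairs without reads in each of the 6 libraries (bars, coloured by group). Right, the same percentage in 10 equal bins of guide pairs ranked on day 0 reads for the 4 later libraries, which falls from 85.5% to 10.5% in day 14 replicate 1 and from 80.9% to 7.9% in irradiated replicate 2.

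The first comparison asked which knockouts were depleted or enriched during standard growth. Among the genes of the core replication machinery, knockouts of Pola1, the catalytic subunit of the polymerase that starts DNA strands, were at a log2 change of -0.46 (SE 0.21, n = 2 libraries per group) at day 14 against day 0, and lower in 4 of 4 library comparisons. Chek1, the checkpoint kinase that restrains cells with damaged or unreplicated DNA, stood at -0.49 (SE 0.28). On the other side, Polm, a gap-filling polymerase of end joining, stood at 0.63 (SE 0.29), and Xrcc6, the Ku70 subunit that binds broken ends, at 0.51 (SE 0.20, 95% interval 0.10 to 0.93). None of these passed the test. Without the incomplete day 14 replicate 1 they were at -0.24 (Pola1), -0.03 (Chek1), -0.04 (Polm) and 0.16 (Xrcc6). Of the 25 genes picked by the naming rule that lay at least 0.3 from 0, 19 kept less than 50% of their change without that library. edgeR called 0 of 459 genes, with 18 below an unadjusted p of 0.05 where 23 are due to chance, and DESeq2 called 0, with 12 below. The smallest adjusted p in edgeR was 0.815.

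The 13 measured members of non-homologous end joining split into 7 lower and 6 higher at day 14, with a median of -0.004 and a mean of 0.05. The ligase gene Lig4 was at -0.13, its partner Xrcc4 at 0.05, Xrcc5 (Ku80) at 0.04, Nhej1 (XLF) at 0.01, Paxx at 0.34 and the nuclease gene Dclre1c (Artemis) at -0.22. Homologous recombination had 12 of 30 members lower, with Brca1 at -0.13 and Brca2 at 0.26, and the MRE11 complex with the damage kinases had 4 of 9 lower, with Nbn at -0.43 (-0.07 without day 14 replicate 1) and Atm at 0.20. In the 53BP1 and shieldin list, which holds factors that protect broken ends from resection, 7 of 12 members were lower, among them Mad2l2 at -0.32 and Shld2 at -0.25, with Trp53bp1 at 0.20. Alternative end joining had 5 of 11 members lower, with Polq at 0.07 and Xrcc1 at 0.47. In the ATR and 9-1-1 checkpoint 7 of 12 were lower, including Topbp1 at -0.28 and Hus1 at -0.26, and in the Fanconi anemia list 11 of 22. With day 14 replicate 1 left out, Paxx was at 0.01, Brca2 at 0.00, Atm at -0.08, Trp53bp1 at 0.10, Mad2l2 at -0.15, Shld2 at -0.16, Topbp1 at -0.11, Hus1 at -0.13 and Xrcc1 at 0.33.

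Base excision repair had 20 of 27 members higher, with the glycosylase genes Neil2 at 0.44 and Smug1 at 0.31, and nucleotide excision repair 13 of 20, with the damage sensor Xpc at 0.41 (SE 0.17) and Gtf2h3 at 0.45. These 4 genes were lower in day 0 replicate 1 than in day 0 replicate 2, and without replicate 1 they were at 0.15, 0.16, 0.30 and 0.31. Members of mismatch repair were higher in 7 of 10 cases, of translesion synthesis in 10 of 16, of the structure-specific nucleases in 12 of 18, of SMC5/6 and cohesin in 8 of 16, and of chromatin remodelling in 12 of 16. All 4 members of the p53 list were higher, with Trp53 itself, which these cells lack, at 0.14 (95% interval -0.25 to 0.53), or -0.07 without day 0 replicate 1. The 4 members of RNase H2 and R-loop processing were also higher, with Rnaseh2a at 0.24 (-0.05 without day 14 replicate 1). In core DNA replication 9 of 25 members were lower and 16 higher, with a mean between -0.12 and 0.18 by its 95% interval. The median of all genes was 0.06, so most genes lay above 0, and the counts of higher members are not set against that share. Camera placed the core DNA replication list below the other genes, with an adjusted p of 0.703 (limma). No list passed, the smallest adjusted p being 0.430 with camera and 0.641 with fry, and 0 members passed in any list when adjusted over the list alone. Without day 14 replicate 1 the nucleotide excision repair list was at a camera adjusted p of 0.0119, in a range of 0.0119 to 0.964 over the alternatives. Without day 14 replicate 2, edgeR called 22 genes, among them Chek1 at -1.17, Polm at 1.09 and Xrcc6 at 0.80, a fit in which day 14 rests on the library that lacked 54.1% of guide pairs.

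**Figure D2:**
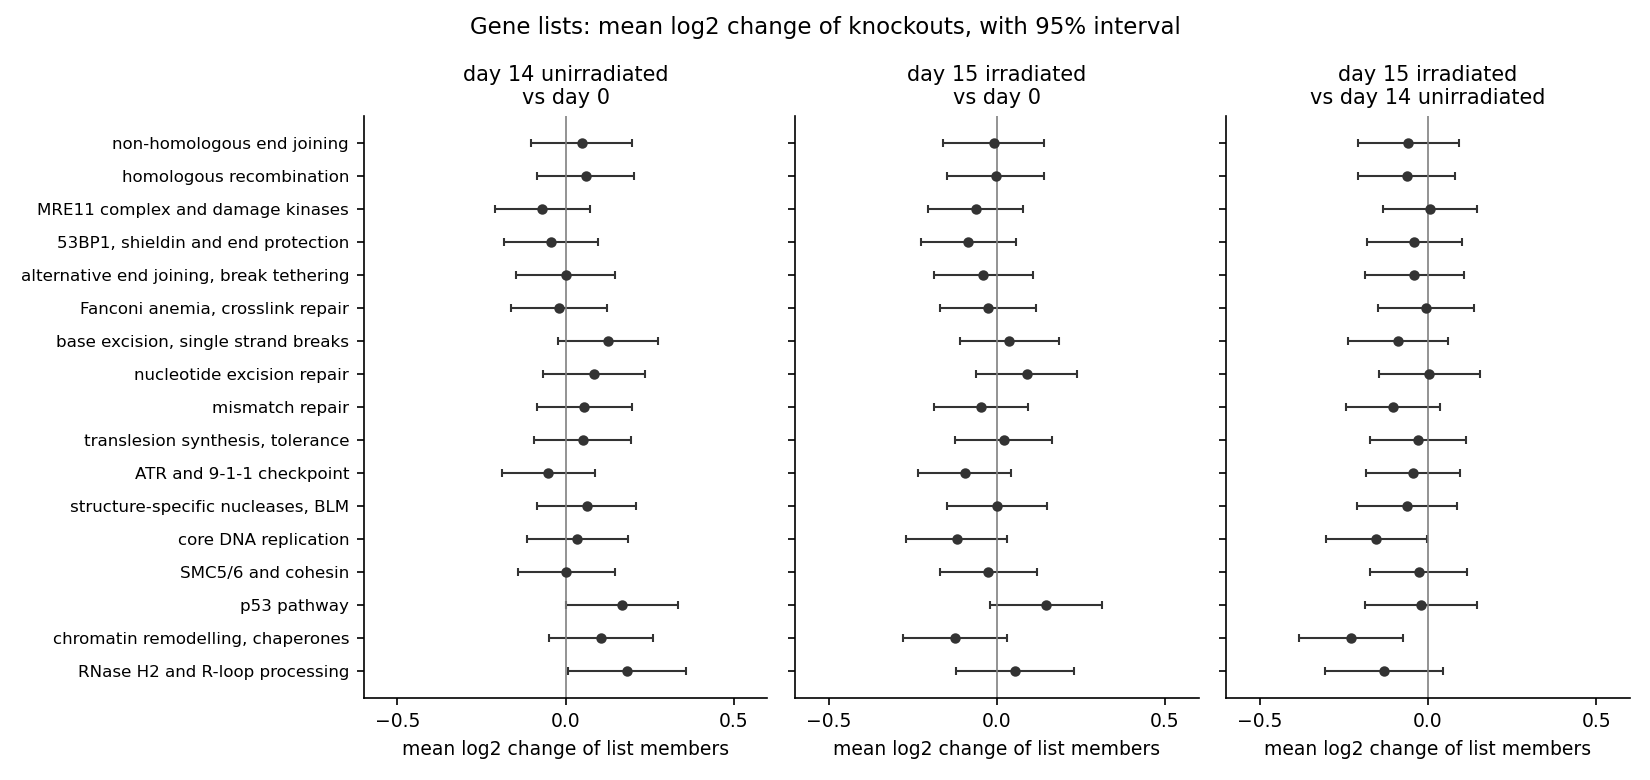
Mean log2 change of the members of each of the 17 gene lists (points) with its 95% interval (bars) in the 3 comparisons of 2 libraries per group. The chromatin remodelling list lies between -0.38 and -0.08 in irradiated against day 14 cells, and the core DNA replication list between -0.12 and 0.18 in day 14 against day 0 cells.

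The second comparison set the irradiated cells against day 0. Pola1 was at -0.61 (SE 0.21, 95% interval -1.05 to -0.18) and lower in 4 of 4 library comparisons, and Hus1, a subunit of the 9-1-1 checkpoint clamp, at -0.53 (SE 0.19). The replication genes Mcm6 and Gins2, both parts of the replicative helicase, were each at -0.49, and Asf1a, a histone chaperone, was at -0.52. Without the incomplete irradiated replicate 2, Pola1 was at -0.42, Hus1 at -0.38, Mcm6 at -0.65, Gins2 at -0.14 and Asf1a at -0.21, and 14 of 27 genes picked by the naming rule at least 0.3 from 0 kept less than 50% of their change. Higher values were found for Smug1 (0.52, SE 0.18), Neil2 (0.43), Cetn2 (0.45) and Xpc (0.39), the last pair being partners in the recognition of DNA damage. All 4 were lower in day 0 replicate 1 than in day 0 replicate 2, and without replicate 1 they were at 0.36, 0.15, 0.29 and 0.27. None of these passed, as edgeR called 0 of 459 genes with 12 below an unadjusted p of 0.05, and DESeq2 called 0 with 14 below.

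End joining genes, whose products rejoin the double-strand breaks that X-rays make, were at 0.05 for Lig4, 0.21 for Xrcc4, -0.06 for Xrcc5, 0.15 for Xrcc6, 0.04 for Nhej1, 0.25 for Paxx and -0.27 for Dclre1c. Of the 13 members 6 were lower and 7 higher, with a median of 0.03 and a mean of -0.01. Atm was at 0.18, Trp53bp1 at 0.15, Brca1 at -0.09, Brca2 at 0.07, Polq at 0.27 and Trp53 at 0.36 (95% interval -0.03 to 0.75). Leaving out a library moved several of these: without day 0 replicate 1 Trp53 was at 0.15, Xrcc4 at 0.05 and Xrcc6 at 0.01, without irradiated replicate 1 Polq was at 0.02, and without irradiated replicate 2 Paxx was at -0.01 and Atm at -0.11. Homologous recombination had 16 of 30 members lower, among them the BRCA2 partner Palb2 at -0.45 (-0.18 without irradiated replicate 2), and mismatch repair 5 of 10. In core DNA replication 16 of 25 members were lower, with a mean between -0.27 and 0.03, and camera gave an adjusted p of 0.0531, or an adjusted p of 0.922 with an estimated correlation. Nucleotide excision repair had 15 of 20 members higher, with a camera adjusted p of 0.301, and the ATR and 9-1-1 list 7 of 12 lower. Without day 0 replicate 2 both the replication and the nucleotide excision repair list were at an adjusted p of 0.0237, in ranges of 0.0237 to 0.922 over the alternatives. That fit leaves day 0 replicate 1 as the only baseline, the library in which 264 of 927 position 2 guides stood lower than the rest by a log2 difference of -0.84, and without day 0 replicate 1 the adjusted p were 0.387 and 0.897. No list passed, the smallest adjusted p with fry being 0.366, and 0 members passed in any list when adjusted over the list alone.

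The third comparison, irradiated against unirradiated cells, addressed which knockouts respond to radiation beyond growth itself. Knockouts of chromatin remodelling and histone chaperone genes were lower after irradiation in 15 of 16 cases, with a median of -0.23 and a mean between -0.38 and -0.08. Irradiated against day 0, 11 of 16 were lower, with a mean between -0.28 and 0.03 (camera adjusted p = 0.159). At day 14 against day 0, 12 of 16 were higher, with a mean between -0.05 and 0.26. The difference therefore draws on both groups. Against day 14, the 3 members of smallest p belong to the INO80 complex, which moves nucleosomes at forks and breaks. They were Actr5 at -0.46 (SE 0.18), Ino80 at -0.50 (SE 0.22) and Ino80b at -0.54 (SE 0.26). Without day 14 replicate 1 they were at -0.23, -0.40 and -0.08. The complex was not tested as a list of its own, and its subunits Actr8 and Ino80c, named after their values were seen, were at -0.04 and 0.19. The list passed with camera at an adjusted p of 0.00271, and was at an adjusted p of 0.999 with an estimated correlation. It was at an adjusted p of 0.641 with fry, all from limma. The median of all genes was -0.08 in this comparison, and 13 of the 16 members lay below it. Without day 14 replicate 1 the camera adjusted p was 0.23, and without irradiated replicate 2 it was 0.22, within a range of 0.00168 to 0.999 over all alternatives, so that leaving out either of the incomplete libraries ended the call.

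Core DNA replication had 22 of 25 members lower, with Mcm6 at -0.58 and Mcm3 at -0.29, and 19 lay below the median of all genes. Its mean lay between -0.30 and 0.00, and the camera adjusted p was 0.119. No single gene passed. The smallest p belonged to Ube2t, the ubiquitin-conjugating enzyme of the Fanconi anemia pathway, at 0.57 (SE 0.21, 95% interval 0.13 to 1.01), followed among the listed genes by Shprh, a ubiquitin ligase of damage tolerance, at -0.49. The excision repair genes Ercc5 and Ercc8 were at -0.41 and 0.47. Without day 14 replicate 1, Mcm6 was at -0.21, Shprh at -0.16, Ercc5 at -0.18, Ercc8 at 0.13 and Ube2t at 0.32, and Ube2t was at 0.26 without irradiated replicate 1. Of 26 genes picked by the naming rule at least 0.3 from 0, 13 kept less than 50% of their change without day 14 replicate 1, and 5 without irradiated replicate 2. edgeR called 0 of 459 genes, with 13 below an unadjusted p of 0.05, and DESeq2 called 0, with 10 below.

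The end joining genes were at 0.19 for Lig4, 0.17 for Xrcc4, -0.09 for Xrcc5, -0.36 for Xrcc6, 0.03 for Nhej1, -0.09 for Paxx and -0.05 for Dclre1c, and 8 of 13 members of the list were lower. Atm was at -0.02, Trp53bp1 at -0.05, Brca1 at 0.04, Brca2 at -0.20, Polq at 0.20 and Trp53 at 0.22. Leaving out day 14 replicate 1 put Xrcc6 at -0.01, Paxx at 0.24, Atm at 0.27, Brca2 at 0.06 and Trp53 at 0.11, and without irradiated replicate 1 Polq was at -0.05. Base excision repair had 20 of 27 members lower, homologous recombination 19 of 30, the structure-specific nucleases 12 of 18, mismatch repair 8 of 10 and RNase H2 with R-loop processing 4 of 4. The median of all genes was -0.08, so most genes lay below 0, and these counts are not set against that share. In the MRE11 and kinase list 5 of 9 were lower, with a median of -0.02 and a mean of 0.01, and in nucleotide excision repair 9 of 20. None of these lists passed, and 0 members passed in any list when adjusted over the list alone. The median 95% half-width of a gene's change was 0.40.

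Interactions were tested for 105111 pairs of genes. In the irradiated libraries the pair of Mutyh, a glycosylase of base excision repair, and Rfwd3, a ubiquitin ligase of crosslink repair, was at -7.38 on the log2 scale against day 14 (95% interval -8.57 to -6.18) and at -6.77 against day 0 (-7.93 to -5.61). The pair of Cul4b, a ubiquitin ligase scaffold, and Xab2, a factor of splicing and excision repair, was at -5.71 and -5.59. Both rested on 1 guide pair each, which had 32029 and 28163 reads in day 0 replicate 1. Neither pair passed, and edgeR called 0 pairs in each of the 3 comparisons. Well-calibrated p-values would put 5256 pairs below an unadjusted p of 0.05 by chance. The edgeR counts below it were 472 (day 14 against day 0), 353 (irradiated against day 0) and 909 (irradiated against day 14). limma-trend called 0, 1 and 1 pairs, with 232, 297 and 965 below, and without either day 0 replicate edgeR called 1 pair in each irradiated comparison, Mutyh with Rfwd3 in each case. The next pair by p against day 14 was Ap5s1 with Rad1 (-1.43). At day 14 against day 0 the 3 of smallest p were Msh3 with Wdr48 (1.46), Cyren with Shld2 (1.23) and Cbx8 with Trp53 (1.48), and none of these passed.

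Of the 89 gene pairs with a commonly described interaction, 75 were measured, and 0 passed in any comparison, whether adjusted over the list alone or over all pairs, with 1, 0 and 0 below an unadjusted p of 0.05. Of the 46 pairs described as negative, 20 lay below 0 at day 14 against day 0, 21 in irradiated cells against day 0 and 21 against day 14. Of the 29 described as positive, 12, 19 and 15 lay above 0. The median 95% half-width of an interaction was 1.34, and changes of 16-fold were not recovered in thinned real counts. Far fewer pairs had an unadjusted p below 0.05 than chance would give, so the p-values of this test ran too large. The lack of calls is therefore no sign that interactions are absent. The spread was estimated over all 6 libraries, including the 2 incomplete ones. Without the 2 incomplete libraries edgeR called 158, 1219 and 200 pairs, in fits where each later group is a single library and the spread comes from the day 0 libraries.

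Single guides, each summed over all its partners, gave smaller errors, with a median 95% half-width of 0.20. At day 14 against day 0, guide 1 of Rnf111, a SUMO-directed ubiquitin ligase, fell by 0.58 (95% interval -0.69 to -0.46, edgeR adjusted p = 0.00479), and guide 1 of Sfpq, an RNA-binding protein that takes part in end joining, fell by 0.40 (adjusted p = 0.0363), both lower in 2 of 2 day 14 libraries. Against day 0 replicate 2 the other 3 guides of Rnf111 lay between -0.13 and 0.05 at day 14, and those of Sfpq between -0.33 and 0.04. After irradiation guide 1 of Cebpg, a transcription factor of the stress response, rose by 1.69 against day 0 (95% interval 1.42 to 1.96, adjusted p = 0.000838) and by 1.76 against day 14 (adjusted p = 0.000633), being higher in 2 of 2 irradiated libraries. The other position 1 guide of Cebpg was at 0.02 and 0.27 in the irradiated libraries against day 0 replicate 2. Against day 14, 8 guides were called, all higher after irradiation and all at position 1, among them guide 2 of the checkpoint kinase gene Atr at 0.63 (adjusted p = 0.0491), guide 1 of Rnf111 at 0.57, guide 1 of Sfpq at 0.42, guide 2 of Psme4 at 0.35, guide 1 of Huwe1 at 0.34, and guide 2 of Ppp4r2 and guide 1 of Pds5b at 0.43 each. These values share the day 14 libraries with the comparison against day 0. Apart from the guide of Cebpg, the difference came from lower day 14 values. Against day 0 replicate 2 these guides lay between -0.66 and -0.26 at day 14, and between -0.04 and 0.14 in the irradiated libraries. In all, 2, 1 and 8 of 1849 guides passed in the 3 comparisons. Without day 0 replicate 2 there were 336 guides past the threshold at day 14 and 326 after irradiation against day 0, and 6 after irradiation without day 0 replicate 1. At day 14 there was 1 without any one of the 4 later libraries, and against day 14 leaving out any library gave 1 to 5. In day 0 replicate 1, 264 of 927 position 2 guides stood apart from the rest by a log2 difference of -0.84 against day 0 replicate 2.

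**Figure D3:**
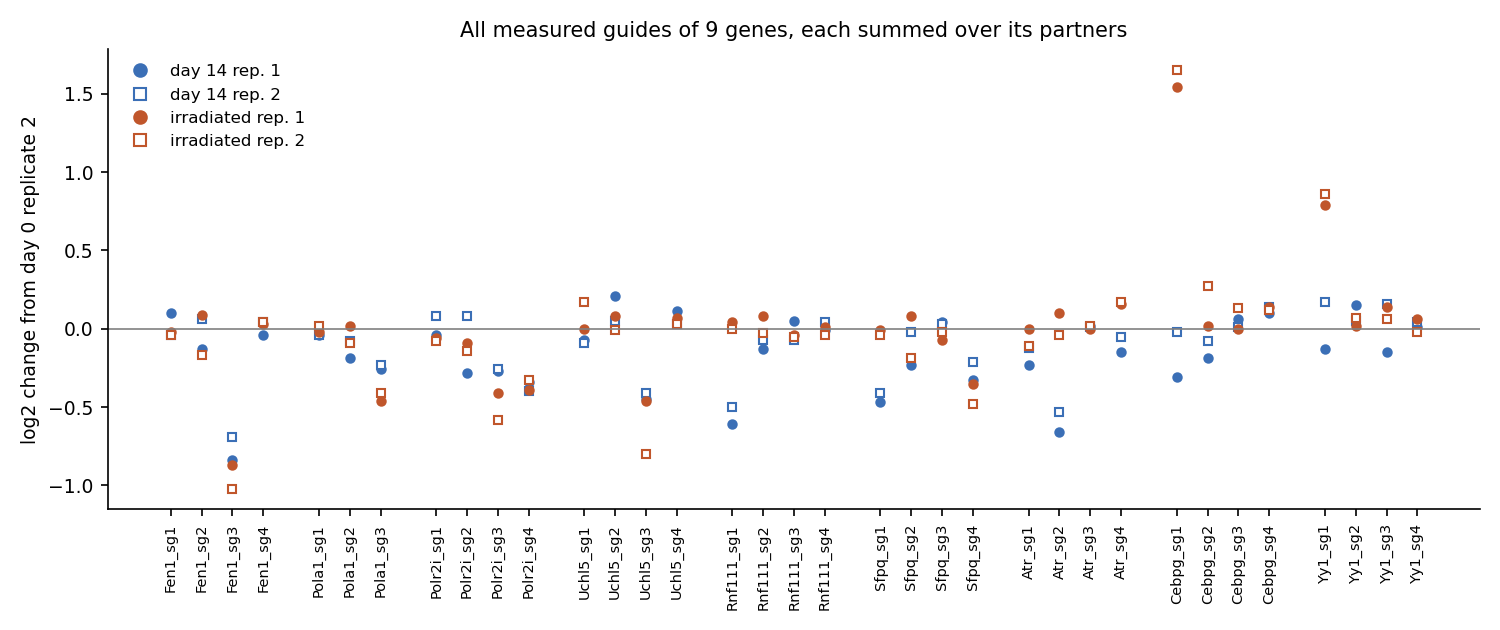
Log2 change from day 0 replicate 2 of all measured guides of 9 genes, each summed over its partners, in the 2 day 14 libraries (blue) and the 2 irradiated libraries (orange), with filled circles for replicate 1 and open squares for replicate 2. Guide 3 of Fen1 lies between -1.02 and -0.69 in the 4 libraries and guide 1 of Cebpg at 1.54 and 1.65 after irradiation, while the other guides of both genes lie between -0.19 and 0.27.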

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

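The guide level, the rule used on it, the tests on core replication genes, on a shared loss of cells, on selective death and on the most abundant guide pairs were chosen or completed only after the result was seen. The test on read number was fixed before, as was one on selective death that found guide pairs with a core replication gene missing more often by 1.1 percentage points. That one decides nothing if core replication guides do not act. Guides are listed here by a rule that some inert guides can meet by chance, as target guides far outnumber non-targeting ones. How many would do so was not estimated. By the rule, guides summed over all partners moved further than each non-targeting guide of their position. They did so in both libraries of the group and against both day 0 libraries.

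At day 14 this held for 5 guides, all lower and all at position 1, where 25 non-targeting guides ranged from -0.18 to 0.15 in mean log2 change. Guide 2 of Atr was at -0.66, guide 1 of Rnf111 at -0.58, guide 1 of Sfpq at -0.40, guide 2 of Ppp4r2 at -0.37 and guide 2 of Psme4 at -0.34. In the guide test those of Rnf111 and Sfpq passed, while those of Atr and Psme4 had an adjusted p of 0.0745 and that of Ppp4r2 0.121. Against day 0 replicate 2 at day 14, the other 3 guides lay between -0.23 and 0.02 for Atr, -0.13 and 0.05 for Rnf111, -0.33 and 0.04 for Sfpq, -0.17 and -0.01 for Ppp4r2, and -0.12 and 0.16 for Psme4. In the irradiated libraries guide 2 of Atr was at 0.10 and -0.04 against day 0 replicate 2, and guide 1 of Rnf111 at 0.04 and 0.00.

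After irradiation it held for 7 higher guides at position 1, against a range of -0.17 to 0.16 for non-targeting guides. The 6 reported here were guide 1 of Cebpg at 1.70, guide 1 of Yy1 at 1.16, guide 2 of Faap24 at 0.52, guide 1 of Wrap53 at 0.31, guide 2 of Dclre1a at 0.27 and guide 1 of Gtf2h3 at 0.18. These are means over both day 0 libraries, and against day 0 replicate 2 alone guide 1 of Yy1 was at 0.79 and 0.86. The other 3 guides of each gene, against day 0 replicate 2, lay between 0.00 and 0.27 for Cebpg, -0.02 and 0.14 for Yy1, -0.39 and 0.01 for Faap24, -0.08 and 0.11 for Wrap53, -0.15 and 0.07 for Dclre1a, and -0.14 and 0.01 for Gtf2h3. At position 2, where 36 non-targeting guides ranged from -0.29 to 0.53, it held for 5 lower guides. That range includes 11 non-targeting guides that were low in day 0 replicate 1, which raises its upper end and makes the rule harder to meet for higher guides. They were guide 3 of Fen1 at -0.89, of Uchl5 at -0.66, of Polr2i at -0.57, of Pola1 at -0.55 and of Abl1 at -0.43. The other measured guides lay between -0.17 and 0.09 for Fen1, -0.01 and 0.17 for Uchl5, -0.39 and -0.06 for Polr2i, -0.09 and 0.02 for Pola1, and -0.10 and 0.07 for Abl1. Of all these guides only guide 1 of Cebpg passed the guide test in irradiated cells against day 0, with adjusted p of 0.221 for Yy1 and Fen1 and 0.781 for Faap24 and Wrap53.

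Knockouts of core replication genes, most of them needed for growth, were not lower at day 14 as a list. Too little precision to see a 2-fold loss is argued against, since the lower 95% bound of the list's mean is -0.116. Whether most guides leave their target's function intact stays open. Over 21 core replication genes with 4 guides, changes of position 1 and position 2 guides correlated at a mean r of -0.005 in day 14 replicate 2 (95% bootstrap interval over genes -0.161 to 0.118). In the incomplete replicate 1 the mean r was 0.107 (-0.036 to 0.251). A correlation near 0 is also due where guides act but the knockouts do not change growth. That would not hold for genes these cells need for growth, a need that was not tested here. The correlation alone therefore cannot decide this. Over 414 genes with 4 guides the mean r in day 14 replicate 2 was 0.002 (-0.052 to 0.057). At position 1 the changes had a standard deviation of 0.092 over target and 0.079 over non-targeting guides. At position 2 it was 0.072 and 0.075. A few guides could act. At position 2, 4 of 46 core replication guides and 5 of 845 others lay lower in all 4 later than in both day 0 libraries. The margin was a log2 difference of more than 0.2 (Fisher's exact test, two-sided p = 0.00065). At position 1 it was 0 of 50 and 0 of 847. Against day 0 replicate 2 alone it was 4 of 46 and 7 of 845 at position 2 (Fisher's exact test, two-sided p = 0.0016). The test was chosen after the guide values were seen and takes guides as independent, so these p-values are not independent support. Guide sequences were not used here, so whether the mouse-style guides match the human genes stays open.

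Day 14 replicate 1 and irradiated replicate 2 lacked 54.1% and 49.4% of guide pairs. Too few reads is argued against, because day 0 replicate 2 thinned to the depth of day 14 replicate 1 would lack 2.3%. Selective death of knockouts as the cause of most missing guide pairs is argued against as well. Guide pairs of 2 genes were missing less often than those of 2 non-targeting guides of like day 0 abundance. The difference was -5.4 percentage points in day 14 replicate 1 (95% bootstrap interval over 36 control guides -8.4 to -1.9). In irradiated replicate 2 it was -7.0 (-10.6 to -3.5). An average over all guide pairs cannot speak on the death of a few knockouts. Why control guide pairs were missing more often was not tested. A shared loss of cells before the cultures were parted is a candidate explanation, as these libraries correlated with each other by 0.264 more than either did with the other library of its own group, and the share missing fell with day 0 abundance, from 85.5% to 10.5% in day 14 replicate 1. A crossed or shared culture behind the replicate numbers stays open, and the labels do not say how replicates were kept.

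Guide 1 of Mutyh with guide 4 of Rfwd3 had 32029 and 21311 reads at day 0 and 31108 and 30281 at day 14, against 10 and 2 after irradiation, and guide 1 of Cul4b with guide 3 of Xab2 went from 28163, 19781, 18019 and 24241 to 299 and 87. The third most abundant guide pair had 3313 and 3018 reads at day 0. Loss of these double knockouts cannot be told apart from a fault of the guide pair: the other 7 guide pairs of each gene pair were at -0.83 (95% bootstrap interval -1.32 to 2.40) for Mutyh with Rfwd3 and -0.91 (-1.23 to 0.51) for Cul4b with Xab2, too wide to decide, against -12.54 and -7.42 for the guide pairs themselves. Without the incomplete libraries, as irradiated replicate 1 against day 14 replicate 2, the other guide pairs were at -0.4 and -0.8. Reads added outside the cells at a fixed share also stay open, as the share varied by a factor of 2.04 over the 4 unirradiated libraries, against a median of 1.62 and a 95th percentile of 3.38 among the next 100 guide pairs.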

How the results depend on the processing

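The fits without both incomplete libraries, the crossed pairing, the count of named genes that kept less than 50% of their change and all tests of single guides were chosen only after the result was seen. The number of genes called was 0 in all but 3 of 56 alternatives. Leaving out a library gave 0 to 22 genes at day 14 against day 0, the 22 without day 14 replicate 2. Without both incomplete libraries edgeR called 1 gene (Ssrp1) at day 14 and 3 (Ssrp1, Mc1r and Ube2t) after irradiation against day 0, where a single library stands for each later group and is assumed to vary like the day 0 pair. These genes were named after their values were seen. For interactions the same fit gave 158 pairs at day 14, 1219 after irradiation against day 0 and 200 against day 14. limma-trend gave 1 pair in each irradiated comparison, the fit of only the 2 groups compared gave 1 against day 14, and leaving out a library gave 0 to 1 in both, the 1 without either day 0 replicate. This pair was Mutyh with Rfwd3 each time. Of the list tests 1 passed; with an estimated correlation 0 did, with changes scaled for doublings 2 (core replication joined in irradiated against day 14 cells, at an adjusted p of 0.0456), and with a library left out 0 to 3 (3 without day 0 replicate 2, 0 without irradiated replicate 2). The chromatin list's adjusted p was 0.999 with an estimated correlation, 0.226 without both incomplete libraries and 0.00299 to 0.23 with a library left out. Guides called at day 14 ranged from 1 to 336 with a library left out, against 7 without both incomplete libraries; after irradiation from 1 to 326 against day 0, against 2, and from 1 to 5 against day 14. The highest guide counts against day 0 came without day 0 replicate 2, a fit whose only baseline is day 0 replicate 1. In that library 264 of 927 position 2 guides stood lower than the rest by a log2 difference of -0.839. How many of them were among the called guides was not counted. The cause of the differences between fits was not tested, and fits with a library left out also rest on fewer libraries.

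With the replicate number as a block, 1 interacting pair, Mutyh with Rfwd3, was called in each irradiated comparison and no other gene, gene pair or list call changed. The guide tests were not run with that block. Deviations of day 14 and irradiated replicates of the same number correlated at -0.537 over genes, and the crossed pairing gave 0 genes and 2 interacting pairs in irradiated against day 14 cells. Of 4002 single gene values under alternatives 380 had the other sign, all between values past the threshold in neither fit, and 9 passed. The filter at a mean count of 100 removed no gene. Reads per gene pair (a median of 599.8) were not the limit, since the coefficient of variation between replicates was 0.473.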

Other observations

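The tests described here were chosen only after the result was seen. Beside the core replication guides, 5 other position 2 guides lay lower than both day 0 libraries by a log2 difference of more than 0.2 in all 4 later ones, namely guide 3 of Abl1, Polr2i and Uchl5 and guide 4 of Polr2i, with guide 3 of Primpol, the primase that restarts stalled forks. The 4 core replication guides belonged to Fen1, the flap nuclease of lagging strand synthesis, Pola1, Gins2 and Rpa2. Polr2i, a subunit of RNA polymerase II, was the gene with both position 2 guides in this set, at -0.27, -0.26, -0.41 and -0.58 for guide 3 and -0.34, -0.40, -0.39 and -0.33 for guide 4 against day 0 replicate 2. For Fen1, guide 3 was at -0.84, -0.69, -0.87 and -1.02, in the order of day 14 replicates 1 and 2 and irradiated replicates 1 and 2, and its other guides stayed between -0.17 and 0.10.

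In day 0 replicate 1, 264 of 927 position 2 guides had a log2 difference from day 0 replicate 2 below -0.25. The median of these guides differed from that of the rest by -0.839. They came as whole genes, with both guides low in 122 of 432 genes and 1 of 2 low in 0 genes, and they included the 11 non-targeting guides numbered 42 to 52. In the other libraries the same guides differed from the rest by 0.058 and 0.008 at day 14 and by 0.009 and 0.063 after irradiation. No test of the origin of this group was run.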
